A study of Rattus norvegicus with 6 samples.

How the data were processed

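Per the labels' protocols, total RNA was taken with Trizol and libraries were made with an Illumina TruSeq RNA kit from 1 ug of RNA; selection or depletion steps are not given in the sources used here. The 6 libraries are labelled PC12 and fall into 2 groups of 3, EC and EN, by the treatment label. The authors deposited 1 table of FPKM (read numbers scaled to gene length and library size) with 33350 gene models, their symbols, coordinates, lengths and biotypes. Per the submitters' processing notes, HISAT2 2.0.5 and the Rnor_6.0 build were used. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. No column of another sample was in the table.

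In every library, each non-zero FPKM times the gene length was a whole multiple of 1 step (100% of values, within 0.001 of a whole number), so whole reads were worked back from it. Their total was 15296193 to 19626012 per library. The library size implied by the FPKM was 0.987 to 1.02 of that total, by a factor whose origin is not given. Gene models without a symbol held 0.829% of the reads and stayed in the tests. Intervals and limits from read numbers cover counting error only.

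The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, for the 12198 genes with a mean of at least 1 FPKM over all 6 libraries. The test was two-sided, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 of 25 lists with at least 5 tested members, and again with an estimated correlation and with fry, which tests whether a list's genes move one way without comparing them with other genes. The level of Ntn1 and the mitochondrial share of reads were compared with exact two-sided permutation tests. The tests, the lists and the alternatives were fixed before the data were examined, except those named below.

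Of 758 list entries, 719 matched a symbol in the table, 4 matched through an older symbol in a RefSeq table of the GRCr8 assembly, 5 repeated another entry and 30 were unmatched. That assembly differs from the table's build, so no coordinate was taken from it. The named genes were chosen by a rule. They are Ntn1 and its receptors, the 8 largest increases and 8 largest decreases past the threshold with no overlap between the groups, a mean of at least 5 FPKM in the higher group and a proper symbol, up to 4 members with the smallest adjusted p of each list with members past the threshold, and the 3 highest members of each marker list of another cell type. Values of some genes that the rule takes are not reported here. Genes named outside it are said to be chosen after their values were seen.

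On simulated data made from these libraries for EN against EC, with 200 of 12198 genes changed, limma recovered 64.2% of genes changed 1.25-fold, 86.6% at 1.5-fold and 97.0% at 2-fold. Of its 173 calls, 4.62% were false, and with no gene changed it made none. The changed genes were drawn from those with a mean of at least 5 FPKM, and genes of similar read number were given 1 median spread. The recovery rates thus do not cover lower genes or genes with a wide spread. Reads were drawn independently for each gene and library, so the false-call rate does not cover differences between libraries that many genes share.

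Alternatives were pseudocounts of 0.1 and 0.5, no expression filter or a mean of at least 5 FPKM, the TPM scale, median centring, quantile normalization, the replicate number as a block, each library left out, no variance trend, array weights and fold limits of 1.5 and 2. After the data were seen, 4 more were added: limma voom on the whole reads, FPKM scaled by total reads, removal of each library's trend with gene length (lowess, span 0.5), and protein-coding models only. The check for samples far from their group needs at least 4 samples per group and was not made on these groups of 3.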

Results

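RNA was sequenced from 6 libraries of rat cells labelled PC12, a line derived from an adrenal pheochromocytoma and widely used as a model of neuronal differentiation. In 3 libraries (EC) the cells had received exosomes, small vesicles that carry protein and RNA between cells, made by control endothelial cells. In the other 3 (EN) the exosomes came from endothelial cells that expressed netrin-1, a secreted axon guidance protein, at a high level. Expression was given as FPKM for 33350 gene models, with coordinates on the Rnor_6.0 build. The reads worked back from these values came to 15416108, 15296193 and 16165804 in EC replicates 1 to 3, and to 17090327, 19626012 and 16654025 in EN replicates 1 to 3, so that each EN library was deeper than each EC library. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. No 2 libraries held identical values, and the chi-square per degree of freedom of their reads was 3.99 to 9.57 for libraries of the same group and 11.3 to 25.1 for libraries of different groups.

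The comparison of EN with EC asks how the recipient cells' transcripts differed when the endothelial cells that made the exosomes had high netrin-1. Transcripts of cholesterol synthesis were lower in EN, with 24 of 28 measured genes past the test, a median log2 change of -0.54 and decreases in mean FPKM of up to 2.03-fold (Tm7sf2). Several glycolytic enzymes and the glucose transporter gene Slc2a1 were higher, by 1.38-fold for Slc2a1. Matrix genes such as Thbs1 and Fn1 and the Schwann cell and glial genes Egr2 and S100b were lower, Egr2 by 1.53-fold in mean FPKM. Of the DCC, neogenin and UNC5 receptor genes for netrin-1, only Unc5b and Unc5c were high enough to be tested. Unc5b was 1.18-fold higher, a call lost in 4 of 6 fits with 1 library left out, and Unc5c did not pass. In the wider list of netrin ligands and receptors, Mcam and Ntn4 were lower. In all, 1754 of 12198 genes passed (limma, Benjamini-Hochberg adjusted p under 0.05), 883 higher and 871 lower in EN, with a median absolute log2 change of 0.29. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, while folds given for single genes are ratios of mean FPKM. On the log2(FPKM + 1) scale, 120 of these genes differed by at least 1.5-fold and 22 by at least 2-fold (10 higher and 12 lower). Tm7sf2, Scd1 and Adamts1, at log2 changes of -0.97, -0.98 and -0.99, are not among the 22, nor is Egr2, at -0.55, among the 120. The number of genes depended on single libraries: it was 347 without EC replicate 2, 409 without EC replicate 3, 446 without EN replicate 1 and 345 without EN replicate 2. Without EN replicate 1, 39.5% of the genes past the test were higher, against 50.3% with all libraries. Among the 82 named genes past the test, the 39 with an adjusted p of 0.0102 or less kept it with each library left out in turn, and the other 43, from 0.0107 upward, lost it without at least 1 library.

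The sterol genes that fell cover most of the pathway from acetyl-CoA to cholesterol. Hmgcs1, which makes HMG-CoA (chromosome 2, 52431601 to 52445055), went from 185.0 ± 4.82 FPKM in EC to 104.6 ± 2.92 in EN (SD, n = 3 each), a log2 change of -0.82 (SE 0.038, limma adjusted p = 3.18e-04). Idi1, the isopentenyl-diphosphate isomerase (chromosome 17, 57976268 to 57984036), went from 87.8 ± 0.591 to 49.5 ± 1.246 FPKM. A gene model on the other strand overlaps Idi1, and the sources used here do not say whether reads were counted by strand. Insig1, which holds the sterol-sensing machinery in the endoplasmic reticulum (chromosome 4, 342302 to 350515), went from 181.2 ± 4.35 to 109.9 ± 1.78 FPKM. Scd1, a fatty acid desaturase (chromosome 1, 264160129 to 264172729), went from 41.2 ± 1.04 to 20.4 ± 0.963 FPKM, a 2.02-fold decrease in the mean. The EN libraries were below all EC libraries in each of these 4 genes. With limma p adjusted over the list alone the count was again 24 lower, and no list member passed as higher. The list as a whole was lower relative to other genes (camera with a preset correlation of 0.01, adjusted p = 1.50e-22; adjusted p = 0.078 with an estimated correlation). The 4 members that did not pass were Srebf2, Pmvk and the sterol exporters Abca1 and Abcg1, with log2 changes of -0.09, 0.09, -0.17 and 0.08 (named after their values were seen).

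**Figure D1:**
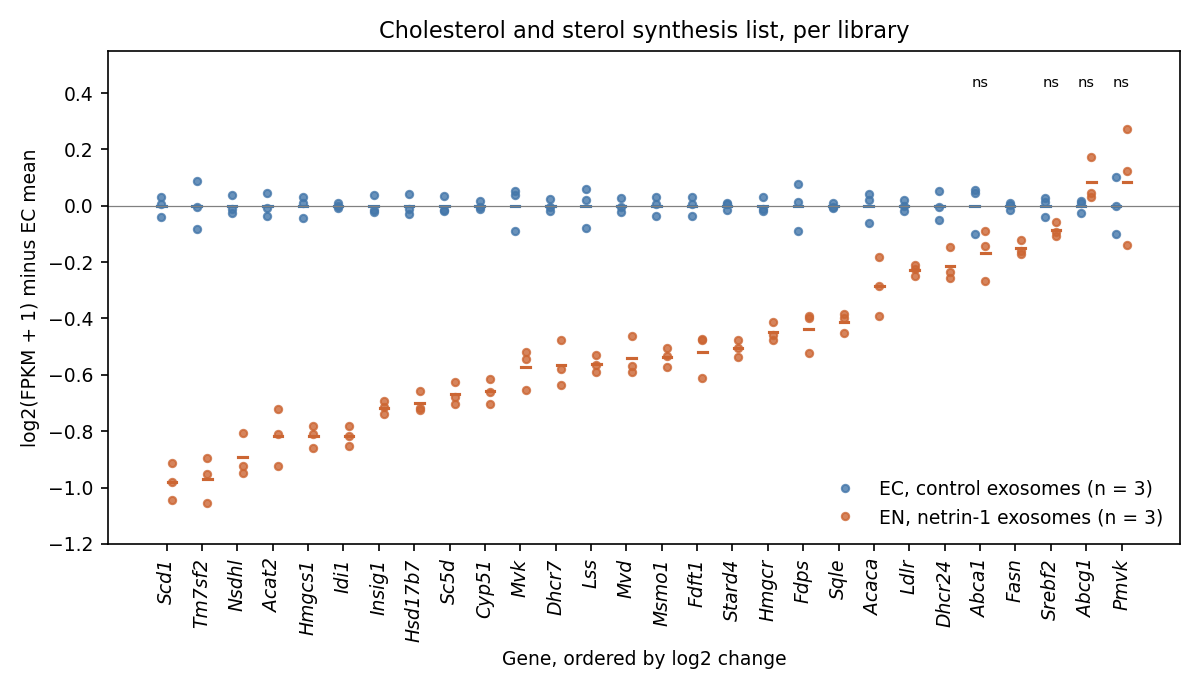
Each point is 1 library's log2(FPKM + 1) for a gene of the cholesterol and sterol synthesis list, minus the mean of the 3 EC libraries for that gene; short lines are group means, and ns marks the 4 genes that did not pass the test. In the 24 genes that passed, all 3 EN libraries lie below all 3 EC libraries.

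In the hypoxia and glycolysis list, 11 of 32 measured genes were higher, 1 was lower and 20 did not pass (14 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.14. The genes that rose encode the glucose transporter Slc2a1 and 10 glycolytic enzymes. Slc2a1 went from 14.5 ± 0.398 to 20.1 ± 0.192 FPKM (SD, n = 3 each; log2 change 0.44, SE 0.043), the hexokinase gene Hk2 from 24.8 ± 0.710 to 32.0 ± 1.10, and the pyruvate kinase gene Pkm from 1116 ± 32.2 to 1401 ± 27.7. Pkm has a second gene model of the same symbol in the table, so its reads may be divided. The aldolase gene Aldoc moved the other way, from 39.3 ± 1.33 to 22.2 ± 0.557 FPKM (log2 change -0.80, SE 0.043). Apart from Slc2a1, hypoxia-responsive genes that do not encode glycolytic enzymes did not pass: Vegfa had a log2 change of 0.23, Car9 of -0.06 and Adm of 0.09 (all 3 named after their values were seen). The list passed as a whole (camera adjusted p = 5.12e-04; adjusted p = 0.269 with an estimated correlation), in every fit with 1 library left out. The number of higher genes fell to 5 without EC replicate 2, EC replicate 3, EN replicate 1 or EN replicate 2. With quantile normalization the list's median log2 change was 0.069, with 9 genes higher and 1 lower.

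Stress-response lists were higher by small amounts. In the heat shock and oxidative stress list, 4 of 22 genes were higher, 1 was lower and 17 did not pass (8 and 1 adjusted over the list alone), with a median of 0.10 and a camera adjusted p of 0.032 (adjusted p = 0.269 with an estimated correlation). Its risers were led by the antioxidant enzyme genes Nqo1, from 290.2 ± 16.5 to 402.3 ± 8.99 FPKM, and Hmox1, from 112.8 ± 4.41 to 157.9 ± 11.3 FPKM (SD, n = 3 each). Mt2A, a metallothionein, rose by 0.21 and the malic enzyme gene Me1 fell by 0.32 on the log2 scale, with adjusted p of 0.029 and 0.021, against 0.0995 for Mt2A without EC replicate 3 and 0.082 for Me1 without EC replicate 2. The unfolded protein and amino acid stress list had 7 of 32 genes higher, 1 lower and 24 that did not pass (8 and 1 adjusted over the list alone), a median of 0.06 and a camera adjusted p of 0.046 (adjusted p = 0.272 with an estimated correlation). The serine hydroxymethyltransferase gene Shmt2 went from 74.4 ± 3.70 to 95.3 ± 1.10 FPKM. Cebpb, Calr and Trib3 rose by 0.34, 0.17 and 0.33 on the log2 scale, with adjusted p of 0.014, 0.026 and 0.026. They were 0.059 for Cebpb without EC replicate 3, and 0.104 for Calr and 0.095 for Trib3 without EN replicate 2. In the apoptosis and p53 list, 3 of 27 genes were higher, none was lower and 24 did not pass (4 and 0 adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.046 (adjusted p = 0.269 with an estimated correlation). The 3 were Aen, from 31.0 ± 1.29 to 39.8 ± 1.62 FPKM, the cell cycle inhibitor gene Cdkn1a, from 73.5 ± 4.37 to 92.4 ± 2.33, and Phlda3, from 113.5 ± 12.9 to 157.0 ± 13.2. The adjusted p was 0.057 for Cdkn1a without EC replicate 2 and 0.081 for Phlda3 without EC replicate 3. All 3 stress lists lost their call without EC replicate 1 (adjusted p = 0.083 for each) and without EN replicate 3 (adjusted p of 0.072 for heat shock and 0.078 for the other lists). The unfolded protein list also lost it without EC replicate 3 (adjusted p = 0.066) and the apoptosis list without EN replicate 1 (adjusted p = 0.080). Changes of filter, scale or gene set also ended these calls. With a mean of at least 5 FPKM the adjusted p was 0.076 for heat shock and 0.091 for the unfolded protein list, with quantile normalization it was 0.059 for heat shock, and with protein-coding models alone it was 0.056 for the other 2 lists. For the apoptosis list it was also 0.057 without a filter, 0.052 on the TPM scale and 0.054 with total-read scaling. The numbers of higher genes also rested on single libraries. For the unfolded protein list they were 4 without EC replicate 1, 1 without EC replicate 3 and 2 without EC replicate 2, EN replicate 1 or EN replicate 2. For heat shock there were 2 without EC replicate 2, EC replicate 3, EN replicate 1 or EN replicate 2, and for apoptosis 1 without EC replicate 2 or EN replicate 2 and 5 without EN replicate 3.

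Among extracellular matrix and integrin genes, 9 of 36 were lower, 3 were higher and 24 did not pass (12 lower and 6 higher adjusted over the list alone), with a median log2 change of -0.10. Thbs1, which encodes thrombospondin 1 (chromosome 3, 109862117 to 109873466), went from 118.4 ± 3.03 to 69.7 ± 3.60 FPKM (SD, n = 3 each; log2 change -0.76, SE 0.046). Fibronectin (Fn1) went from 271.9 ± 9.29 to 203.6 ± 2.49 FPKM, Sparc from 175.0 ± 3.78 to 128.6 ± 4.88, and tenascin C (Tnc) from 427.2 ± 3.78 to 360.7 ± 6.99. A gene model on the other strand overlaps Fn1. Genes that rose included the laminin chain gene Lama5 and the integrin gene Itga3, by 0.26 and 0.19 on the log2 scale (both chosen after their values were seen). The list passed as a whole (camera adjusted p = 0.012; adjusted p = 0.272 with an estimated correlation), but not without EC replicate 1 or EN replicate 3, where the highest adjusted p was 0.072. Singly, 5 genes were lower and 0 higher in limma without EC replicate 2, EC replicate 3, EN replicate 1 or EN replicate 2.

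Schwann cell and glial markers were measured as another cell type's genes. Of 12 tested, 6 were lower, 1 was higher and 5 did not pass (7 lower and 2 higher adjusted over the list alone), with a median log2 change of -0.30 and a camera adjusted p of 0.032 (adjusted p = 0.269 with an estimated correlation; 0.078 at most without EC replicate 1 or EN replicate 3). Egr2, a transcription factor of myelination, went from 11.0 ± 0.888 to 7.19 ± 0.204 FPKM (SD, n = 3 each), and S100b from 131.3 ± 1.15 to 95.4 ± 7.47. Ngfr, the low-affinity neurotrophin receptor, went the other way, from 99.9 ± 4.96 to 114.3 ± 2.05 FPKM (adjusted p = 0.032, and 0.116 without EC replicate 2). The number of lower genes was 4 to 6 with 1 library left out, and Ngfr no longer passed without EC replicate 2, EC replicate 3, EN replicate 1 or EN replicate 2. Sox10, a transcription factor of neural crest and glia, was at 102.5 ± 1.02 FPKM in EC and 104.8 ± 8.61 in EN and did not pass.

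Marker levels stood apart from the cell type on the labels in both groups (single genes here were named after their values were seen). Of 26 genes of catecholamine synthesis and chromaffin identity in the table, 7 had a mean of at least 1 FPKM, and the median was 0.182 FPKM. A mean of at least 10 FPKM was reached by 4 of these 26 genes and by 5 of 18 Schwann and glial genes. It was also reached by 4 of 20 fibroblast and mesenchymal genes, a list with a median of 0.129 FPKM. Tyrosine hydroxylase (Th) averaged 1.47 FPKM and Dbh 0.196. Chga and Chgb, which encode granins of chromaffin granules and belong to the vesicle list, averaged 0.037 and 0.019. No read was counted for Hand2 in any library, which allows up to 0.046 FPKM over all 6 (3 reads). The median of the 18 Schwann and glial genes in the table was 3.72 FPKM, and it was above the chromaffin median in 6 of 6 libraries. Because of these levels, the libraries are named here only as labelled PC12. Between the groups, 1 of 7 tested chromaffin genes was lower, none was higher and 6 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.667, with a positive median of 0.05 but a negative camera direction, and lower with fry, adjusted p = 0.0055). The lower one was Pts, an enzyme of tetrahydrobiopterin synthesis, from 13.4 ± 0.125 to 9.24 ± 0.372 FPKM (SD, n = 3 each).

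**Figure D2:**
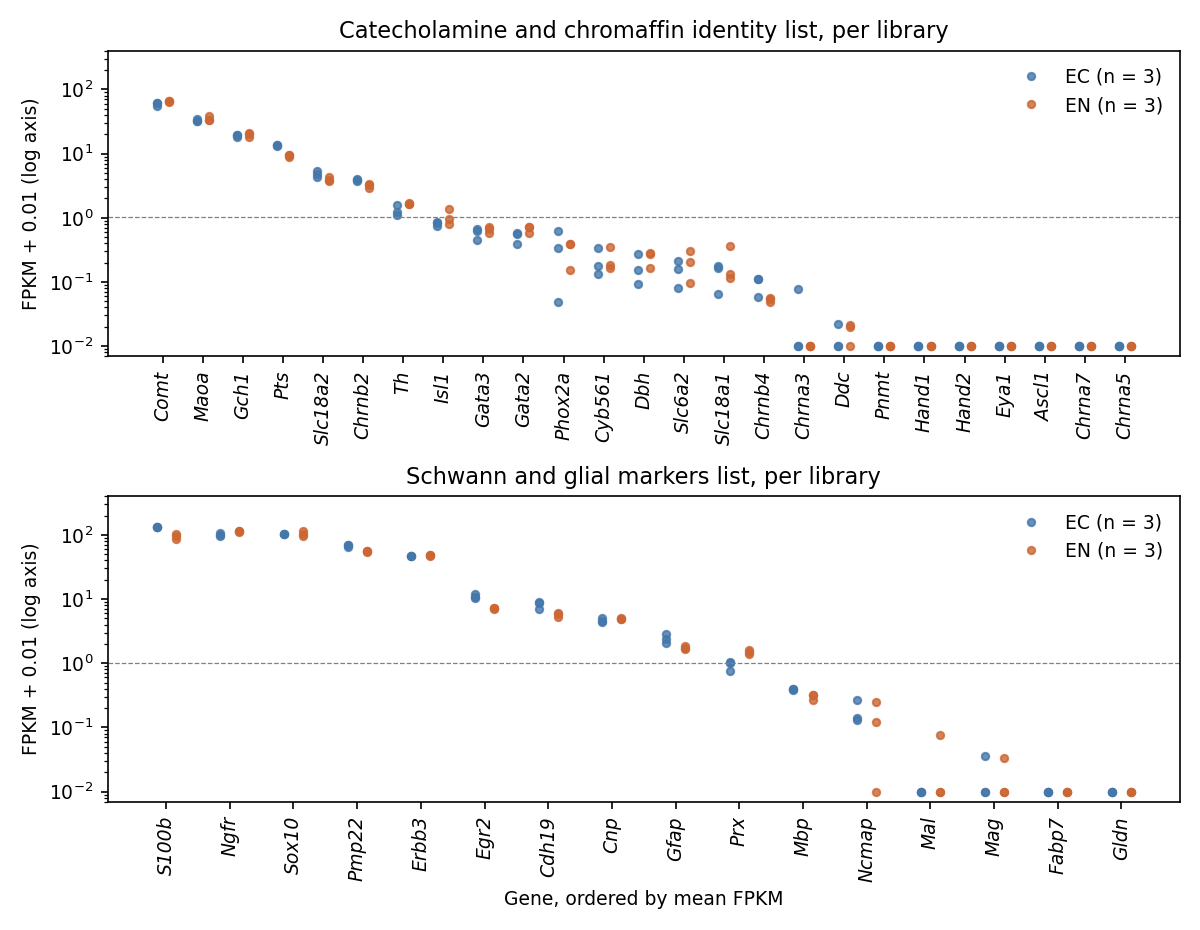
Each point is 1 library's FPKM plus 0.01, on a log axis, for the genes of the chromaffin list (top) and of the Schwann and glial list (bottom) found in the table, without a few genes that are not shown; the dashed line is at 1 FPKM. Over the whole lists, 7 of 26 chromaffin genes and 12 of 18 Schwann and glial genes average at least 1 FPKM.

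The netrin receptor genes were read as a group. Unc5b, which encodes a dependence receptor for netrin-1 (chromosome 20, 30339673 to 30406295), went from 37.6 ± 0.883 to 44.5 ± 1.19 FPKM (SD, n = 3 each; log2 change 0.24, SE 0.040, limma adjusted p = 0.016, and 0.070 without EC replicate 2). The Unc5b call was also lost without EC replicate 3, EN replicate 1 or EN replicate 2. Unc5c was at 4.81 ± 0.231 and 4.48 ± 0.403 FPKM and did not pass. Unc5a was at 0.447 ± 0.124 and 0.430 ± 0.088 FPKM. Unc5a, Dcc, Neo1 and Unc5d were under the expression minimum and were not tested. Dcc had 2 reads and Neo1 1 read over all 6 libraries, and Unc5d none, which allows up to 0.0099 FPKM (3 reads). In the list of netrin ligands and receptors, 1 of 7 tested genes was higher, 2 were lower and 4 did not pass, also adjusted over the list alone (median -0.09, camera adjusted p = 0.306, but lower with fry, adjusted p = 0.0023). The lower ones were the adhesion receptor gene Mcam, from 50.1 ± 1.35 to 34.5 ± 1.54 FPKM, and the netrin family gene Ntn4, from 15.1 ± 0.562 to 10.8 ± 0.397 FPKM. A gene model on the other strand overlaps Ntn4. Netrin downstream signalling genes had 1 of 23 higher, 6 lower and 16 that did not pass (2 and 8 adjusted over the list alone; median -0.07, camera adjusted p = 0.112, but lower with fry, adjusted p = 0.012). Enah, an actin regulator, fell by 0.27, Mapk3 (ERK1) by 0.19 and Ablim1 by 0.43, and the adaptor gene Crk rose by 0.21 on the log2 scale. Their adjusted p lay between 0.017 and 0.029, and each was lost without at least 1 library (adjusted p = 0.069 for Enah without EC replicate 3, 0.099 for Mapk3 and 0.102 for Crk without EC replicate 2, and 0.092 for Ablim1 without EN replicate 2). Of the downstream genes, 2 were lower without EC replicate 1, 1 without EC replicate 2, EC replicate 3, EN replicate 1 or EN replicate 2, and 9 without EN replicate 3.

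Netrin-1 itself was read as a check on transfer of its mRNA with the exosomes. Ntn1 (chromosome 10, 54761871 to 54967585) had 2 reads in EC replicate 1, 2 in EN replicate 2 and none in the other libraries. Its mean was 0.023 ± 0.040 FPKM in EC and 0.018 ± 0.031 in EN (SD, n = 3 each), and the difference of -0.0072 on the log2 scale was within that spread (exact two-sided permutation p = 1; 3 against 3 cannot go below 0.1). The difference turned positive, 0.025, without EC replicate 1, and 0.0055 without EN replicate 1 or EN replicate 3. A count of 0 in EN replicate 1 allows up to 0.092 FPKM at its depth (3 reads; counting error only). No difference in Ntn1 mRNA was therefore detectable at this depth, and the protein was not measured here.

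Neuronal and guidance lists held members that moved in both directions, and none passed camera as a whole. Of 32 other axon guidance genes, 3 were higher, 3 were lower and 26 did not pass (7 and 4 adjusted over the list alone; median 0.02, camera adjusted p = 0.667). The neuropilin gene Nrp1 went from 39.9 ± 2.02 to 31.4 ± 0.752 FPKM (SD, n = 3 each), while Efnb1, Sema6b and Plxna1 rose by 0.37, 0.32 and 0.17 on the log2 scale. The adjusted p of these 3 was 0.018, 0.022 and 0.031, against 0.070, 0.089 and 0.114 without EN replicate 2. Of 14 neuronal cytoskeleton and neurite genes, 2 were higher, 5 were lower and 7 did not pass, also adjusted over the list alone (median -0.07, camera adjusted p = 0.382, but lower with fry, adjusted p = 0.028). The adhesion gene Ncam1 and Dclk1 fell by 0.23 and 0.28, and Basp1 and Map1a rose by 0.34 and 0.19 on the log2 scale. Their adjusted p was 0.013, 0.021, 0.020 and 0.030, and it rose to 0.065 and 0.082 for Ncam1 and Dclk1 without EN replicate 2 and to 0.072 and 0.108 for Basp1 and Map1a without EC replicate 2. Gap43, a growth cone gene named after its value was seen, had 1 read in all 6 libraries together. Of 14 synaptic and dense-core vesicle genes, 2 were higher, 1 was lower and 11 did not pass, also adjusted over the list alone (median 0.01, mean -0.0021, camera adjusted p = 0.983 with a negative direction). Cplx2 went from 23.8 ± 0.683 to 29.6 ± 0.820 FPKM, and Snap25 from 5.33 ± 0.268 to 3.48 ± 0.332 (adjusted p = 0.017, and 0.069 without EC replicate 3). Syngr1 rose by 0.27 on the log2 scale (adjusted p = 0.047, and 0.140 without EC replicate 2). With 1 library left out, the numbers that passed ran from 0 to 6 higher and 1 to 3 lower for axon guidance, 0 to 2 higher and 0 to 3 lower for the cytoskeleton list, and 1 to 2 higher and 0 to 1 lower for the synaptic list.

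Growth factor response genes also split. In the immediate early and ERK feedback list, 6 of 32 were higher, 4 were lower and 22 did not pass (10 and 4 adjusted over the list alone; median 0.07, camera adjusted p = 0.306). Egr1, an early growth response transcription factor (chromosome 18, 27657628 to 27661429), went from 38.7 ± 1.17 to 19.0 ± 0.790 FPKM (SD, n = 3 each; log2 change -0.99, SE 0.047, limma adjusted p = 3.18e-04). The ERK inhibitor gene Spry2 went from 81.4 ± 1.69 to 64.0 ± 2.18 FPKM, and Etv4, an ERK-induced transcription factor, rose from 27.5 ± 1.43 to 39.7 ± 2.79. Of 15 injury and regeneration genes, 1 was higher, 3 were lower and 11 did not pass (1 and 4 adjusted over the list alone; median -0.13, camera adjusted p = 0.259, but lower with fry, adjusted p = 0.0076). Socs3, a feedback inhibitor of cytokine signalling, rose from 19.6 ± 2.42 to 34.6 ± 4.23 FPKM. Flrt3, Klf7 and Cebpd fell by 0.38, 0.20 and 0.30 on the log2 scale with adjusted p of 0.013, 0.032 and 0.047, and their adjusted p was 0.057 and 0.103 for Flrt3 and Klf7 without EC replicate 3 and 0.148 for Cebpd without EC replicate 2. In the neurotrophic factor list, 1 of 19 was higher, 4 were lower and 14 did not pass, also adjusted over the list alone (median 0.06 but a negative mean of -0.05 and a negative direction, camera adjusted p = 0.806). Ciliary neurotrophic factor (Cntf; chromosome 1, 229599009 to 229601032) went from 13.2 ± 1.71 to 6.03 ± 0.889 FPKM, and pleiotrophin (Ptn) from 583.8 ± 15.8 to 417.9 ± 24.5. Igf1 and Gfra1 fell by 0.58 and 0.27 on the log2 scale (adjusted p of 0.031 for both, against 0.107 for Igf1 without EC replicate 3 and 0.108 for Gfra1 without EN replicate 2). In the PI3K-AKT-FOXO list, 3 of 26 were higher, 1 was lower and 22 did not pass (4 and 1 adjusted over the list alone; median -0.02, camera adjusted p = 0.667). The higher ones were Klf2, Cdkn1a and Trib3, and Foxo1 was the lower one. Klf2 went from 4.001 ± 1.03 to 7.48 ± 0.667 FPKM (adjusted p = 0.025, and 0.087 without EN replicate 2), and Foxo1 fell by 0.28 on the log2 scale (adjusted p = 0.029, and 0.103 without EC replicate 2). With 1 library left out, the numbers that passed ran from 2 to 8 higher and 3 to 4 lower for the immediate early list, 0 to 3 lower for the injury list, 0 to 2 higher and 2 to 4 lower for the neurotrophic list, and 0 to 4 higher and 0 to 2 lower for the PI3K-AKT-FOXO list.

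Proliferation and inflammation lists did not pass camera or fry. Of 39 cell cycle genes, Bub1 alone passed, at -0.16 on the log2 scale (adjusted p = 0.039, and 0.122 without EC replicate 3), none was higher and 38 did not pass. The balance depended on processing, with 4 higher and 0 lower with total-read scaling, 3 and 1 on the TPM scale, 9 and 3 with array weights and 2 and 1 with limma voom on the reads. No cell cycle gene passed in limma with p adjusted over the list alone, where 13 had an unadjusted p under 0.05 and limma voom on the reads called 3 (median 0.02, camera adjusted p = 0.321). Of 23 type I interferon genes, 1 was higher, 2 were lower and 20 did not pass, also adjusted over the list alone (median -0.03, camera adjusted p = 0.529). Ifit2 went from 16.1 ± 0.293 to 11.8 ± 0.029 FPKM (SD, n = 3 each). Stat2 fell by 0.23 and Tap1 rose by 0.29 on the log2 scale (adjusted p of 0.031 and 0.044, against 0.110 and 0.141 without EN replicate 2). Of 17 NF-kappaB and inflammation genes, 2 were higher, 1 was lower and 14 did not pass (4 and 2 adjusted over the list alone; median 0.01, camera adjusted p = 0.667). The chemokine gene Cxcl1 went from 19.3 ± 0.804 to 11.7 ± 1.80 FPKM (adjusted p = 0.011, and 0.051 without EC replicate 2). Tnfaip2 and Ccl2 rose by 0.25 and 0.19 on the log2 scale (adjusted p of 0.038 and 0.046, against 0.124 and 0.153 without EN replicate 2). With 1 library left out, the numbers that passed ran from 0 to 2 higher and 0 to 1 lower for the cell cycle, 0 to 1 higher and 1 to 2 lower for interferon, and 0 to 4 higher and 0 to 2 lower for NF-kappaB.

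Markers of other cell types were measured to see whether RNA of other cells moved with the groups. Of 6 tested endothelial markers, Egfl7 alone was higher, at 4.12 ± 0.688 FPKM in EC and 6.09 ± 0.599 in EN (SD, n = 3 each; adjusted p = 0.041, and 0.126 without EN replicate 2), none was lower and 5 did not pass (2 and 1 adjusted over the list alone). The Egfl7 call was lost in 5 of 6 fits with 1 library left out. With the replicate number as a block, no endothelial marker passed in either direction. Flt1 was at 3.17 and 4.10 and Ramp2 at 2.97 and 2.60 FPKM in EC and EN. The endothelial list had a median of -0.0049, a positive mean of 0.05 and a camera adjusted p of 0.667 with a positive direction. None of 8 tested fibroblast and mesenchymal markers passed in limma, adjusted over all genes or over the list alone, where 2 had an unadjusted p under 0.05 and limma voom on the reads called none over all genes and 2 over the list alone (median 0.04, camera adjusted p = 0.569). The highest were Prrx1 at 121.1 and 134.8, Pdgfra at 65.0 and 64.6 and Twist1 at 40.1 and 46.7 FPKM. Macrophage and leukocyte markers had 2 tested members, and canonical histone genes 3, too few for a list test. None passed over all genes in limma or limma voom, and unadjusted p was under 0.05 for 1 and 0 of them (1 macrophage marker was lower adjusted over the list alone). The highest macrophage markers were Cd14 at 34.2 ± 1.09 and 31.0 ± 0.372 FPKM, Cd68 at 4.17 ± 0.591 and 4.22 ± 0.455, and Itgax, which is under the expression minimum, at 0.591 ± 0.048 and 1.20 ± 0.184.

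Mitochondrially encoded mRNAs were lower in EN as a list, with all 11 below EC in the mean, a median log2 change of -0.31 and a camera adjusted p of 0.0019 (adjusted p = 0.533 with an estimated correlation, 0.126 with fry and 0.059 with quantile normalization). Singly, Mt-nd1 and Mt-nd2 fell by 0.46 and 0.38 on the log2 scale and 9 did not pass (3 lower adjusted over the list alone). Their adjusted p was 0.032 and 0.044, against 0.108 for Mt-nd1 without EN replicate 2 and 0.136 for Mt-nd2 without EC replicate 2. The number of genes that passed was 9 without EN replicate 3, 10 with array weights, 5 with limma voom on the reads and 0 without EC replicate 2, EC replicate 3, EN replicate 1 or EN replicate 2. Reads of the mitochondrial chromosome took 5.87% ± 0.379 of the reads in EC and 4.87% ± 0.568 in EN (SD, n = 3 each; exact two-sided permutation p = 0.2, smallest possible 0.1).

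**Figure D3:**
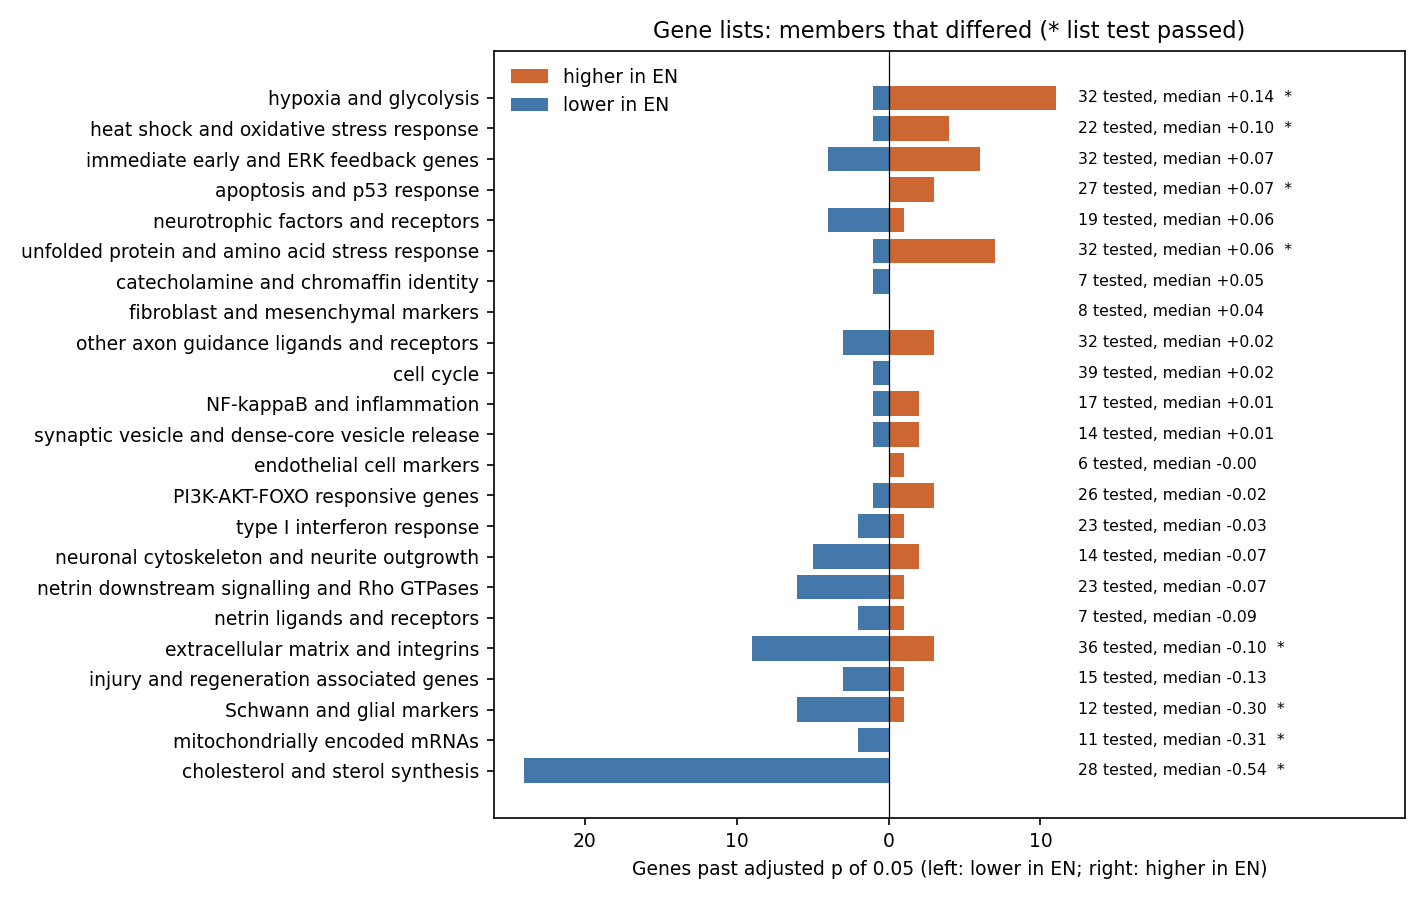
Bars give the number of genes of each list that passed the test, lower in EN to the left and higher in EN to the right; the text gives the number of tested members and their median log2 change, and an asterisk marks the 8 of 23 lists past the camera test with a preset correlation, of which 0 passed with an estimated one. The sterol list stands out with 24 of 28 genes lower.

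The largest changes by fold, among genes with no overlap between the groups, included genes with a wide spread. Ebna1bp2, a ribosome assembly factor (chromosome 5, 137670123 to 137674802), was at 1.74 ± 2.06 FPKM in EC and 20.5 ± 13.9 in EN (SD, n = 3 each; log2 change 2.87, SE 0.752, limma adjusted p = 0.048). Its EN libraries ranged from 4.49 to 29.7 FPKM. Hnrnpab, an RNA-binding protein gene, was at 14.4 ± 13.0 and 56.1 ± 10.6 FPKM, and Tma7 fell from 11.4 ± 8.99 to 1.013 ± 0.711 FPKM. The adjusted p of Ebna1bp2 was 0.144 without EC replicate 2, and that of Hnrnpab and Tma7 was 0.124 and 0.075 without EN replicate 1. Rpl27-l1, a processed pseudogene that can share reads with Rpl27, went from 3.81 ± 0.358 to 8.57 ± 2.69 FPKM (adjusted p = 0.024, and 0.084 without EC replicate 3). Closer spreads were seen for Brms1, from 3.40 ± 0.615 to 9.996 ± 1.80 FPKM, the IGF-binding protein gene Igfbp4 (chromosome 10, 86950557 to 86962578), from 17.7 ± 1.08 to 31.7 ± 2.13, and the DNA repair gene Ercc1, from 62.5 ± 6.38 to 109.5 ± 7.84. Hmga1, a chromatin protein gene, rose by 0.79 on the log2 scale (adjusted p = 0.015, and 0.051 without EN replicate 2). Gene models on the other strand overlap Hnrnpab, Tma7 and Ercc1, and Hnrnpab and Brms1 each have a second model of the same symbol, so their reads may be divided. Among the genes named from the lists, Nrp1, Efnb1, Dclk1, Klf7, Pdgfra, Ramp2 and Itgax overlap another gene model on the same strand, and Dclk1, Ramp2, Sox10 and Egfl7 one on the other strand. Among the decreases, the matrix protease gene Adamts1 (chromosome 11, 25342126 to 25350974) went from 57.4 ± 1.60 to 28.4 ± 0.740 FPKM, a 2.02-fold decrease in the mean. The proteasome subunit gene Psmd14 went from 55.7 ± 3.65 to 29.1 ± 1.81 FPKM and the sulfotransferase gene Sult1a1 from 5.14 ± 0.863 to 2.18 ± 0.300. Tm7sf2, a sterol reductase gene, went from 24.9 ± 1.54 to 12.2 ± 0.723 FPKM, and another gene model on the same strand overlaps it.

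The 6 libraries separated by group. The first principal component held 33.2% of the variance, with EC libraries between -18.3 and -7.98 and EN libraries between 8.34 and 18.4. The second held 20.03%, with EN replicate 3 at -20.1 and EC replicate 1 at 13.6 as its ends. Pearson correlations across genes were 0.983 to 0.987 within groups and 0.977 to 0.983 between groups. In 4627 of 12198 genes (37.9%) the 3 EN values did not overlap the 3 EC values, against 10% by chance.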

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

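The tests on whole reads, on total-read scaling, on gene length and on protein-coding models alone, and all alternatives for the separation of the libraries, were chosen after the data were seen; the others were planned. None of the 1754 genes past the threshold changed sign in any alternative in which it was tested. Their number was 22 with a limit of 2-fold (10 higher, 12 lower), 120 with 1.5-fold (59 and 61), 866 without an expression filter (399 and 467), 1019 without the variance trend (510 and 509) and 3849 with array weights (1928 and 1921). With 1 library left out it ran from 345 to 2067 (143 to 1031 higher, 185 to 1036 lower), where fewer samples leave less power, yet it was 1614 without EC replicate 1 and 2067 without EN replicate 3, and the cause of that difference was not tested. All other alternatives gave 1723 to 2359 genes. Scaling by total reads put 58.6% of the calls higher, against 50.3%. Where 91 named genes had values, median centring and both pseudocounts kept every call and direction. The drop without a filter comes with 20495 genes tested and a p adjusted over them; the cause of the other shifts was not tested.

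Of 23 lists, 8 passed, against 3 to 8 with 1 library left out, 0 with an estimated correlation and 12 with fry. The cholesterol and the glycolysis lists passed in every other alternative in which lists were tested. Lists were not tested without the variance trend or with array weights. Directions that turned belong to results that did not pass the main test, though the chromaffin list passed fry as lower (adjusted p = 0.0055). The synaptic list turned positive without a filter (adjusted p = 0.725), with a mean of at least 5 FPKM (0.734), with quantile normalization (0.969), with the replicate block (0.991), with libraries left out (0.682 to 0.977) and with the length trend removed (0.895). So did the chromaffin list without a filter (0.861) and the PI3K-AKT-FOXO list with a mean of at least 5 FPKM (0.717), and the NF-kappaB list turned negative without EN replicate 1 (0.978; 0.508 to 0.978 with 1 library left out). Log2 changes near 0 turned for Ramp2 without EC replicate 3 (-0.216 to 0.040 with 1 library left out) and for Sox10 without EN replicate 1 (-0.031 to 0.086). Pdgfra turned on the TPM scale (0.0076), with quantile normalization (5.79e-04), with total-read scaling (0.015), with the length trend removed (0.013) and without EC replicate 3 or EN replicate 1 (0.0059 and 0.017; lowest with 1 library left out -0.033). Cd68 turned with array weights (-0.0025), with the length trend removed (-0.0031) and without EC replicate 2 or EN replicate 1 (-0.060 and -0.054; highest with 1 library left out 0.103). The Ntn1 difference ran from -0.033 to 0.025 with 1 library left out, which 4 reads in all cannot settle. The gap between the mean correlation within and between groups was 0.0018 without a filter, 0.0076 with at least 5 FPKM, 0.0031 on whole reads with limma voom, and 0.0035 to 0.0055 with 1 library left out.

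The replicate numbers showed no clear pairing of the samples. The deviations of same-numbered libraries correlated at 0.088, -0.095 and -0.020, and EC replicate 2 correlated best with EN replicate 3 (0.134). Deviations from a mean of 3 libraries depend on each other, so these values cannot exclude that same-numbered samples shared an origin. With the replicate number as a block, limma called 1907 genes, 1482 of them shared with the fit without it, and 7 lists, the unfolded protein list being lost (adjusted p = 0.069). Most simulated changes of 1.5-fold were found in genes of at least 5 FPKM with a typical spread. For genes that did not pass, smaller changes stay open, as do changes of lower or more variable genes.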

Other observations

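The single genes in this paragraph were chosen after their values were seen and stand for no tested group. The acetyl-CoA synthetase gene Acss2 fell by 0.86, the acyl-CoA synthetase gene Acsl3 fell by 0.73 and the sterol isomerase gene Ebp fell by 0.51 on the log2 scale (limma adjusted p = 9.27e-04, 5.84e-04 and 0.0031). Ctgf and Cyr61, matricellular genes known as targets of YAP and TEAD, went from 1319 ± 33.5 to 887.1 ± 20.2 FPKM and from 39.1 ± 0.901 to 22.5 ± 2.61 FPKM (SD, n = 3 each). Annexin A1 (Anxa1) went from 486.9 ± 10.1 to 342.6 ± 2.79 FPKM. Axin2, a target of Wnt signalling, rose from 19.6 ± 1.39 to 33.97 ± 3.44 FPKM, Akr1b8, an aldo-keto reductase gene, from 265.8 ± 4.06 to 397.8 ± 2.72, and the neuronal pentraxin receptor gene Nptxr from 697.3 ± 25.3 to 1068 ± 27.3. Hprt1 differed between libraries of the same group, at 9.91, 0.382 and 42.0 FPKM in EN replicates 1 to 3 against 0.567 to 0.790 in EC, and did not pass (adjusted p = 0.185).

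All tests of the 3 patterns below were chosen after the patterns were seen; the counts over other splits of the libraries were not. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Only the real split, 1 of the 10, reached its 1754 genes, and the highest of the others had 5. Each other split mixes EN and EC libraries, so a difference between EN and EC widens its spread within groups and lowers its count. These counts thus do not show how many genes would be called without a difference. For lists, 1 split reached the real 8, and the highest of the others had 4.

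The first pattern is the lower level of sterol synthesis genes in EN. The list's median log2 change was at most -0.52 under the TPM scale, median centring, quantile normalization and total-read scaling, and whichever library was left out. These values argue against library scaling and against a single divergent library as the whole cause, within limits. Under these scalings the median of all tested genes stayed within -0.0065 to 0.018, so they had little room to move the list. In the 24 genes that passed, all EN libraries lay below all EC libraries. Leaving 1 library out could therefore change the size of the fall but not its direction. A candidate biological explanation is more sterol in the EN cells, which lowers SREBP target genes and raises LXR target genes. The tested LXR targets went both ways, Abca1 at -0.17 (SE 0.078) and Abcg1 at 0.08 (SE 0.054), with a median of -0.042. A median that was not positive had been written down as counting against this explanation. The value is smaller than either SE and neither gene passed, so the explanation is left open. Both groups received exosomes, so the presence of exosomes alone does not separate them. Exosome dose and uptake, and batches of culture or preparation, were not compared here and stay open. What differed between the EN and EC exosomes also stays among the open explanations, and sterols were not measured.

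The second pattern is the low level of chromaffin genes beside a higher median of Schwann and glial genes in all libraries labelled PC12. Only some Schwann genes were high, with 5 of 18 at 10 FPKM or more and 4 under 0.1. Of 20 fibroblast and mesenchymal genes, 4 also reached 10 FPKM, such as Prrx1 at 121.1 FPKM in EC, and 10 were under 0.1. The 18 chromaffin genes that have a model and reads were low as well, with a median of at most 0.702 FPKM in any library. Missing gene models cannot explain these genes by the way they were chosen, so their level is no test of that explanation. A model exists for 26 of the 28 genes, but the number with reads lay between the limits written for a test of missing models. For the genes without a model or without a read, this explanation stays open. A minor admixture of Schwann-like cells in a chromaffin culture was predicted to leave a chromaffin sum above the Schwann sum. The genes summed here did not show this. The summed FPKM of Th, Dbh, Chga and Chgb was at most 0.582% of that of S100b, Sox10, Ngfr and Erbb3. These genes were picked after the levels were seen, so the sum restates the pattern for them and cannot exclude an admixture. Chga and Chgb belong to the vesicle list, and S100b, Ngfr and Sox10 are the highest of the Schwann list. The 4 chromaffin list genes with a mean of at least 10 FPKM were not in the sum. Cells of another identity than chromaffin stay open and untested, since the higher median of the Schwann list in 6 of 6 libraries only restates the pattern. The lists behind the medians were fixed before the data were examined, but the choice of the summed genes was not. Whether the label or the line differs from its description cannot be settled from expression alone.

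The third pattern is a small rise of cytosolic ribosomal protein genes, a group chosen after its values were seen. Of 65 tested, 32 were higher in EN and none was lower in limma (median 0.20 on the log2 scale); without 1 library, EC replicates 1 to 3 and EN replicates 1 to 3 in turn, 29, 4, 4, 6, 3 and 33 were higher. These genes are short, with a median length of 630 bases against 2169 for all tested genes, and log2 change ran weakly against length across 10815 protein-coding genes (Spearman rho = -0.11; genes are not independent replicates), but with the length trend removed the median was still 0.16. The lower mitochondrial share of reads in EN could raise other genes by only 0.015 on the log2 scale. A different response to the EN than to the EC exosomes may remain as a hypothesis. Batches of RNA or library preparation, which the labels do not give, also stay open.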
